A study of Homo sapiens with 24 samples.

How the data were processed

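RNA sequencing libraries were made from cells derived from H9, an established line of human embryonic stem cells, with 4 libraries in each of 6 groups. Ventrally patterned neuronal progenitors were sampled at day 15 (D15) and immature cortical interneurons at day 30 (D30). At each day, control cells named KRAB were set against cells in which CRISPR interference was aimed at ZNF292 with either of the guides ZNF-G1 and ZNF-G2. CRISPR interference uses a catalytically dead Cas9, here named for its KRAB repressor domain, to hold down transcription of a chosen gene. The 4 replicates of a group are described as independent differentiations. The columns of the D30 table carry day 35 in their names while the sample titles and the time point label give day 30. They were assigned by guide and sample number and are called D30.

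The deposited values are raw counts per gene symbol, whole numbers with no normalization by the authors, in 1 table per day with 56609 rows. The authors' notes name the hg38 genome build and the tools cutadapt 3.4, STAR 2.5.4b, featureCounts 1.4.6-p4 and Subread, without giving the role or order of each. Libraries were prepared with a kit that removes ribosomal RNA. The annotation release, the strand setting and the handling of reads with several positions were not given in the sources used here. Total counts per library ran from 10201007 to 30446298. The 56607 distinct row names were matched to GENCODE release 29 on GRCh38 by symbol, which gave 1 gene for 54784, several genes for 105 and none for 1718. Those without a match include 25 distinct names, on 27 rows, that had been turned into dates, as spreadsheet programs do with some gene symbols. They were kept as rows without a gene name.

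Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each day, the 12 libraries were fitted with 3 group means after filterByExpr by group and TMM scaling. The quasi-likelihood F test with robust estimation was used, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. An adjusted p under 0.05 is a call. The contrasts were the mean of both guide effects, each guide against KRAB, and ZNF-G1 against ZNF-G2. A fit of all 24 libraries with 6 group means gave D30 against D15 in KRAB cells and the difference of the guide effect between the days. Log2 fold changes used a prior count of 2. The standard error (SE) given is the log2 fold change without that prior count, divided by the square root of the F statistic. It can be too small where a group has few counts, and is left out for ZNF292. Levels are CPM, the counts of a gene scaled to a common library total with TMM-scaled totals, given as mean ± SD with n = 4 per group. MALAT1 and NEAT1 alone are given in CPM of the library totals without TMM scaling. Percentages of the KRAB level for genes with few counts carry exact binomial intervals at a confidence level of 0.95. A group without counts is given a bound at 3 counts over the group. Intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

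The groups, contrasts, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. Among genes called for both guides together, with the same sign and an unadjusted p under 0.05 in each guide, a mean CPM of at least 2 and an ordinary protein-coding symbol, the rule takes the 8 largest rises and the 8 largest falls of each day. It adds ZNF292, and of the 5 lists with the smallest camera p of a day the 3 members with the smallest adjusted p. For D30 against D15 in KRAB cells it takes 3 such members of each of 5 lists, and for the other contrasts the 3 largest rises and falls. Members of lists named beyond these, and the HOX genes, CLIC5, MEOX1 and ALDH1A1 at D30, RNU6-1, ZNF471 at D15, CAT, PRR3, MALAT1 and NEAT1, were picked after their values were seen. A few genes that the rule takes are not reported here.

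The 28 gene lists were tested with camera on the edgeR fit, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Each test was repeated with the correlation estimated from the data. The self-contained test fry was also run. It asks whether the genes of a list move, on balance, in one direction, and compares no list with other genes. Members were counted as higher or lower over all genes tested and adjusted over the list alone. The lists covered MGE and ventral patterning, interneuron and GABA, neural progenitors, cell cycle, pan-neuronal, synapse and excitability, dorsal pallium and glutamatergic, LGE with CGE and striatal, hypothalamus with diencephalon and eye, and midbrain with hindbrain and floor plate. They further covered neural crest and mesenchyme, epithelium and choroid plexus, pluripotent cells, astrocytes and oligodendrocyte lineage, and endothelium and myeloid cells. The others were the SHH, WNT, and BMP and TGF-beta pathways, the unfolded protein and integrated stress response, p53 targets, hypoxia and glycolysis, cholesterol synthesis, ribosomal proteins, the mitochondrial genome, interferon response, axon guidance and migration, autism and intellectual disability genes, and the neighbours of ZNF292.

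Both guides were compared with the same KRAB libraries, so the overlap of their calls was set against 20 simulations without any guide effect and against splits of the KRAB libraries. Recovery was tested on simulated data with the depth and spread of these libraries, in which 200 genes were changed and genes were drawn independently. At D15, 70.3% of genes changed by 1.5-fold, 85.7% of those changed by 2-fold and 100% of those changed by 4-fold were called, with 11 false calls among 17503 genes. At D30 the shares were 20%, 53.8% and 93.2%, with 3 false calls among 19930 genes. For the difference between the days they were 19.7%, 49.2% and 84.8%, with 4 false calls among 20774 genes.

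The alternatives chosen at the outset were relative log expression size factors, no filter on low counts, a mean CPM of at least 1, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, the replicate number as a block, leaving out each library, a fit over all 24 libraries, the guide libraries as 1 group, a prior count of 0.125 and a test against a fold change of 1.2. After the data had been seen, the libraries of samples 1 and 4 or of samples 2 and 3 alone, these pairs as a block, D30 ZNF-G2 reduced to samples 1 and 4, and an exchange of the rows of PRR3 and PRR34 were added. The groups of samples 1 and 4 and of samples 2 and 3 were formed because the D30 libraries tended to separate in this way, and no label names them. Counts were also recomputed over up to 100 other splits of the libraries into groups of the same sizes. Chromosome arms were not tested, because centromere positions were not used here. Whole chromosomes were set against 10000 random gene sets and 10 Mb windows were described by their medians. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.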

Results

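Gene expression was measured by RNA sequencing in 24 libraries from H9 human embryonic stem cells that had been differentiated toward cortical interneurons of the medial ganglionic eminence (MGE), the ventral part of the embryonic forebrain where many of these cells are born. Ventrally patterned progenitors at D15 and immature interneurons at D30 were each sampled as KRAB control cells and as cells carrying guide ZNF-G1 or ZNF-G2 against ZNF292, which encodes a zinc finger protein. There were 4 libraries per group. Total counts ran from 10201007 to 13593454 in D15 KRAB, from 11650215 to 23239194 in D15 ZNF-G1 and from 12274890 to 20010127 in D15 ZNF-G2. At D30 they ran from 13485355 to 30446298 in KRAB, from 14498644 to 23234770 in ZNF-G1 and from 19980238 to 30222251 in ZNF-G2. Unless a guide is named, log2 fold changes are the mean of both guide effects against KRAB, and adjusted p-values come from the edgeR quasi-likelihood test.

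ZNF292 transcripts were nearly absent from the guide libraries at both days. At D15, ZNF292 (ENSG00000188994.12, chromosome 6, 87152833 to 87264196, plus strand, GRCh38) stood at 111 ± 3.90 CPM (SD, n = 4) in KRAB cells. The 4 ZNF-G1 libraries held 5 ZNF292 counts together and the 4 ZNF-G2 libraries held 1, against 4999 in KRAB. Scaled to depth, this was 0.0599% of the KRAB level with ZNF-G1 (exact interval 0.0194 to 0.14) and 0.0139% with ZNF-G2 (0.000351 to 0.0773). At D30, KRAB cells reached 196 ± 2.39 CPM (SD, n = 4), and the guide groups held 5 and 2 counts against 15016. These were 0.0332% of KRAB (0.0108 to 0.0776) with ZNF-G1 and 0.0103% (0.00124 to 0.037) with ZNF-G2. The fitted log2 fold change was -9.36 at D15 (adjusted p = 3.3e-21) and -10.49 at D30 (adjusted p = 1.09e-11).

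**Figure D1:**
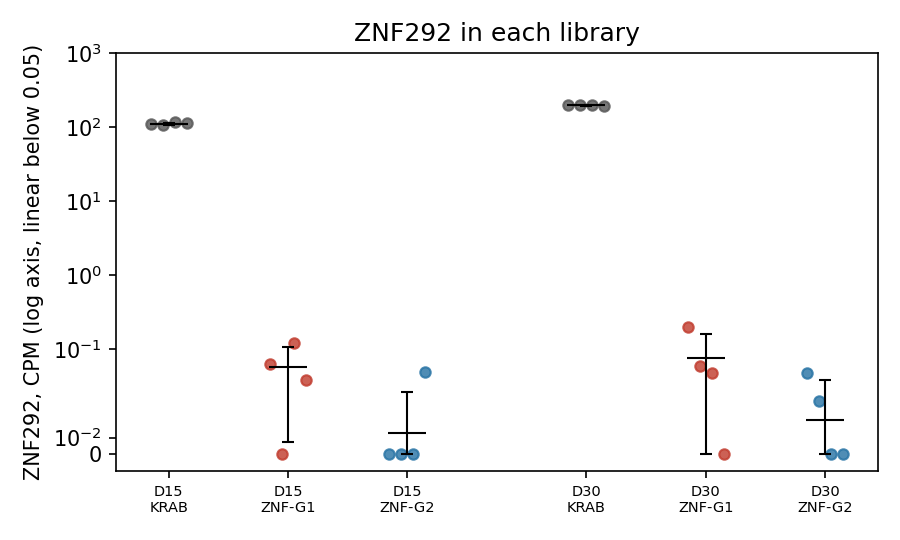
ZNF292 level in each library in CPM, on an axis that is linear below 0.05 and logarithmic above, by group at D15 and D30. All KRAB libraries lie above 100 and all guide libraries below 0.3.

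The first comparison set progenitors with the guides against KRAB progenitors. At D15, most tested genes of the MGE and ventral patterning list were higher with the guides, and most tested mesenchymal genes and p53 targets were lower. For the mean of both guides, p53 targets alone of these lists kept its call with an estimated correlation. Of 18164 genes tested, 4002 were higher and 4309 lower, 692 and 1087 of them by at least 2-fold. LHX8, a homeobox gene of the developing MGE, rose from 1.77 ± 1.04 CPM in KRAB to 23.2 ± 3.14 with ZNF-G1 and 17.4 ± 1.64 with ZNF-G2 (log2 fold change 3.44, SE 0.214, adjusted p = 6.03e-09). HOXA2, a hindbrain patterning gene, fell from 15.1 ± 2.16 CPM in KRAB, where 675 counts were found, to 2 counts over the ZNF-G1 libraries and 1 over the ZNF-G2 libraries. HOXA2 thus stood at 0.177% (exact interval 0.0215 to 0.644) and 0.103% (0.0026 to 0.574) of the KRAB level.

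Among the largest rises at D15, GABRB2, a subunit of the GABA-A receptor, rose from 0.129 ± 0.0672 CPM in KRAB to 4.07 ± 0.96 with ZNF-G1 and 3.70 ± 0.737 with ZNF-G2 (log2 fold change 3.92, SE 0.354, adjusted p = 2.4e-09). The receptor phosphatase PTPRT rose by 3.18, the sialyltransferase ST6GAL2 by 3.02, and NOS2, the inducible nitric oxide synthase, by 3.00. NOS2 reached 74.7 ± 12.3 CPM with ZNF-G1 and 241 ± 49.3 with ZNF-G2, against 16.8 ± 1.44 in KRAB. LHX1, a homeobox regulator of neuronal development, rose by 2.95 and H1F0, a linker histone gene, by 2.92.

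Among the deepest falls at D15 after ZNF292 was RHOJ, which dropped from 52.9 ± 9.69 CPM to 0.418 ± 0.193 with ZNF-G1 and 0.279 ± 0.155 with ZNF-G2 (log2 fold change -6.85, SE 0.17, adjusted p = 6.06e-15). BCHE, which encodes butyrylcholinesterase, had a log2 fold change of -6.83, and the membrane protein gene TMEM132C one of -6.56. The glycosyltransferase gene GALNT5 fell from 9.20 ± 1.48 CPM to 2 counts over ZNF-G1 and 4 over ZNF-G2, against 408 counts in KRAB. APLN, which encodes the secreted peptide apelin, fell from 177 ± 27 CPM to 3.13 ± 0.455 and 3.59 ± 1.19 (log2 fold change -5.69). TCEAL7 had a log2 fold change of -5.57.

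Genes of MGE and ventral patterning moved together at D15. Of the 20 listed, 19 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.73. NKX2-1, which specifies the MGE, rose from 224 ± 11.4 CPM to 580 ± 36.4 and 579 ± 69.1 (log2 fold change 1.37), and SIX3, an anterior forebrain gene, by 0.76. OLIG2 rose by 2.07, GSX2 by 2.56, LHX6 by 1.84 and SHH, the ventralizing signal, by 1.51. The exception was NKX6-2, which fell from 19.3 ± 3.10 CPM to 6.39 ± 2.46 and 2.54 ± 1.06. The camera adjusted p was 1.21e-15, but adjusted p = 0.0639 with an estimated correlation. With an estimated correlation, the adjusted p was 0.0349 for ZNF-G1 alone and 0.0819 for ZNF-G2 alone.

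Regional markers of other parts of the brain shifted too. Of 13 midbrain, hindbrain and floor plate genes tested, 3 rose and 5 fell (median log2 fold change -0.37), among them NKX6-1 at -5.07 and EN1 at -3.33, while LMX1B and CORIN rose (camera adjusted p = 0.000676, adjusted p = 0.123 with an estimated correlation). In 2 of these genes a guide group had no counts, and the median was unchanged with them at their bound. Of 18 genes of the lateral and caudal eminences and striatum, 5 rose and 9 fell, led by MEIS1 at -3.72 and MEIS2 at -2.08, while ISL1 and SP8 rose (adjusted p = 0.00142, adjusted p = 0.0611 with an estimated correlation). Of 21 genes of hypothalamus, diencephalon and eye, 12 rose, among them RAX, SIX6 and FEZF1, and 6 fell, among them NKX2-2 at -4.93 and IRX3 at -3.02, and the list was not called (adjusted p = 0.264). Of 8 dorsal pallium and glutamatergic genes, 3 rose, EMX2 by 2.62, and 2 fell (adjusted p = 0.155).

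Progenitor and neuronal genes split at D15. Of 25 neural progenitor genes, 7 rose, among them the Notch effector HES5 at 1.24, and 10 fell, among them PAX6 at -3.24, the radial glial gene FABP7 at -2.06 and VIM at -0.97 (adjusted p = 0.00155, adjusted p = 0.123 with an estimated correlation). Of 30 pan-neuronal genes, 18 rose, STMN2 by 1.81 and DCX by 0.98, and 6 fell, with the neurofilament gene NEFL at -3.28 (adjusted p = 0.00142, adjusted p = 0.132 with an estimated correlation). Of 37 genes of synapse and excitability, 21 rose and 8 fell, the glutamate receptor gene GRIA1 most at -4.75 (adjusted p = 0.0041, adjusted p = 0.132 with an estimated correlation). The guides differed here. For ZNF-G1 alone the pan-neuronal and synapse lists were called (adjusted p = 0.0349 for each with an estimated correlation), and for ZNF-G2 alone they were not (camera adjusted p = 0.087 and 0.236). Set against ZNF-G2 directly, ZNF-G1 had 19 of 30 pan-neuronal genes higher (adjusted p = 0.0015 with an estimated correlation), and 22 of 37 synapse genes higher and 1 lower (0.000792). Of 50 cell cycle genes, 28 rose and 4 fell, by small amounts with a median of 0.18 (adjusted p = 0.011, adjusted p = 0.757 with an estimated correlation). The interneuron and GABA list went both ways, with 7 of 21 higher, among them GAD1, SLC32A1 and SST, and 8 lower, among them CALB1, ERBB4 and MAF (adjusted p = 0.427). Adjusted over the list alone, the fallen progenitor genes numbered 11, the pan-neuronal rises 19, the cell cycle counts 29 and 5, and the interneuron rises 8, while the synapse counts were the same.

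Most tested genes of the mesenchymal, ribosomal, mitochondrial and interferon lists were lower at D15. Of 17 neural crest and mesenchyme genes tested, 1 rose, TWIST1, and 11 fell (adjusted p = 8.41e-07, adjusted p = 0.175 with an estimated correlation). ACTA2, which encodes smooth muscle actin, fell from 164 ± 35.5 CPM to 2.09 ± 0.382 and 14.5 ± 1.15. SPARC, an extracellular matrix gene, had a log2 fold change of -0.78 and the mesenchymal regulator PRRX1 one of -1.90, and COL3A1 fell from 1630 ± 323 CPM to 219 ± 15.8 and 260 ± 90.2. Of 48 ribosomal protein genes, 41 fell, with a median of -0.26 and RPS19 at -0.68, RPS7 at -0.38 and RPL3 at -0.37 (adjusted p = 2.61e-05, adjusted p = 0.576 with an estimated correlation). All 13 genes of the mitochondrial genome fell, MT-CYB by a log2 fold change of -0.79, MT-ND5 of -0.63 and MT-CO2 of -0.57 (adjusted p = 6.79e-05, adjusted p = 0.387 with an estimated correlation). Of 17 interferon response genes 12 fell, with IFIT2 at -2.34 and B2M, a component of MHC class I, at -1.01 (adjusted p = 0.000659, adjusted p = 0.189 with an estimated correlation). All counts of this paragraph were the same adjusted over the list alone.

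The remaining D15 lists were smaller or mixed. Of 20 BMP and TGF-beta genes, 3 rose and 10 fell, BAMBI by a log2 fold change of -3.17 (adjusted p = 0.0477, adjusted p = 0.16 with an estimated correlation), and 4 of 8 epithelium and choroid plexus genes rose, KRT8 and OTX2 among them (adjusted p = 0.0477, adjusted p = 0.387 with an estimated correlation). In the WNT pathway 7 of 24 rose and 10 fell, WNT7A by a log2 fold change of -4.25 (adjusted p = 0.561). In the SHH pathway 7 of 14 rose and 4 fell, GLI1 at 0.61 and BOC at -2.98 (adjusted p = 0.917). Axon guidance and migration had 12 of 39 higher and 18 lower (adjusted p = 0.175), and the unfolded protein and integrated stress response 4 of 22 higher and 11 lower (adjusted p = 0.561). Hypoxia and glycolysis had 6 higher and 6 lower of 21, cholesterol synthesis 1 and 7 of 22, and autism and intellectual disability genes 21 and 13 of 59. Pluripotent cell genes had 5 higher and 1 lower of 7, astrocyte and oligodendrocyte genes 4 and 4 of 12, endothelial and myeloid genes 1 and 3 of 5, and the neighbours of ZNF292 3 and 4 of 13. The median, mean and camera direction differed in sign for the astrocyte, SHH, hypoxia, autism and neighbour lists. Adjusted over the list alone, the stress response counts were 6 and 12, the hypoxia falls 7 and the hypothalamus rises 13, and all other counts were the same.

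**Figure D2:**
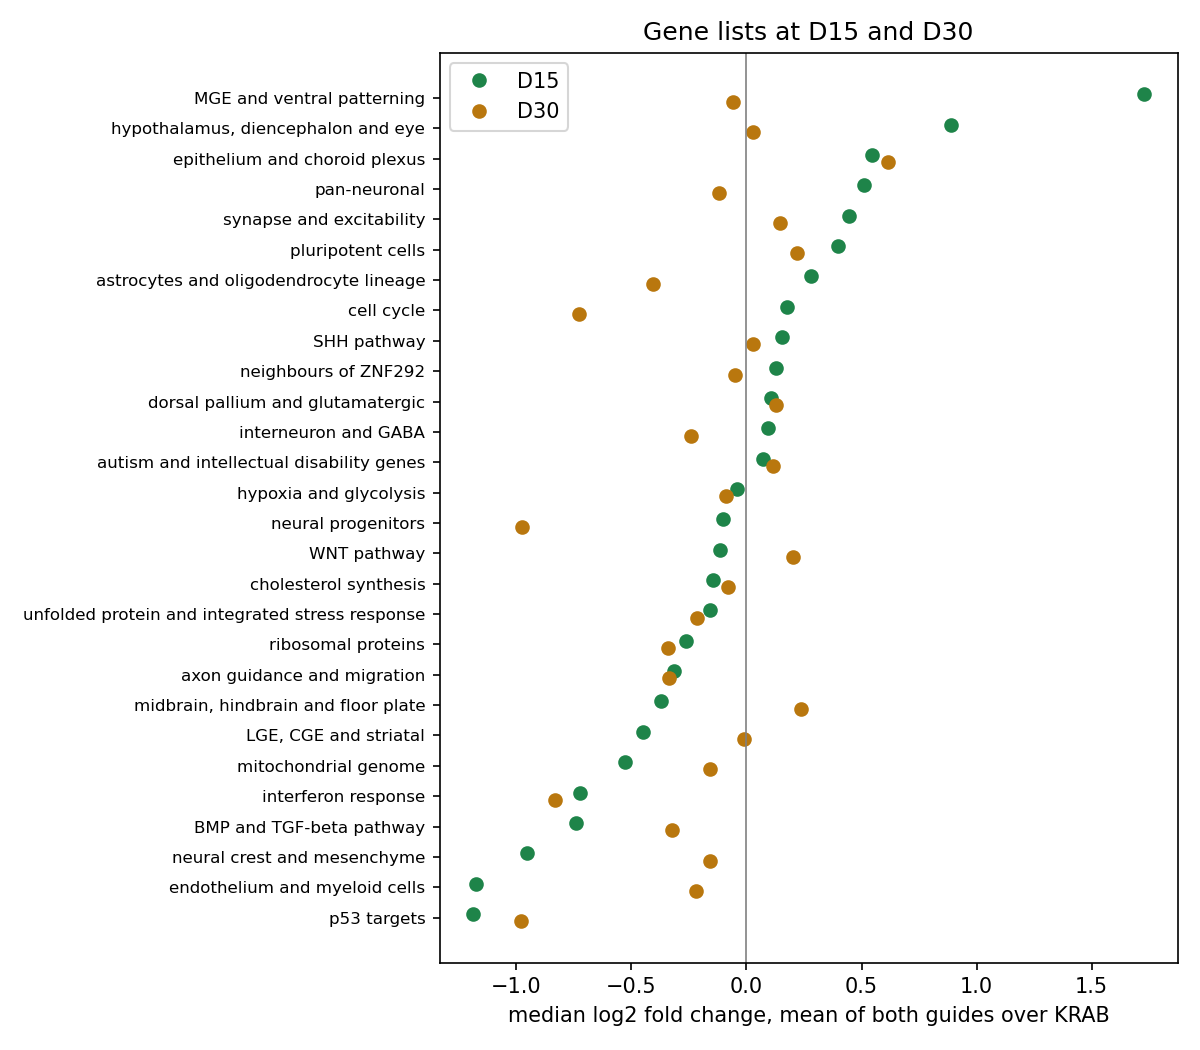
Median log2 fold change of the mean guide effect for each of the 28 gene lists at D15 and D30. The p53 target list has the lowest median at D15 (-1.19) and at D30 (-0.98), and the MGE and ventral patterning list the highest at D15 (1.73) but -0.06 at D30.

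The p53 targets were lower at both days and lowest with ZNF-G1. At D15, 18 of 20 fell with a median log2 fold change of -1.19 (camera adjusted p = 2.65e-40, adjusted p = 0.00269 with an estimated correlation). At D30, 17 of 20 fell with a median of -0.98 (adjusted p = 5.73e-36, adjusted p = 0.00266 with an estimated correlation). Both counts were the same adjusted over the list alone. CDKN1A (chromosome 6, 36676460 to 36687339, plus strand), which encodes the cell cycle inhibitor p21, stood at 509 ± 63.6 CPM in D15 KRAB, 8.56 ± 1.41 with ZNF-G1 and 246 ± 19.4 with ZNF-G2. At D30 CDKN1A stood at 369 ± 22.1, 16.3 ± 3.84 and 87.5 ± 33.1 CPM. At D15, PHLDA3, a p53-induced inhibitor of Akt, had a log2 fold change of -2.47, the death receptor FAS of -2.99 and FDXR, a mitochondrial reductase, of -1.63. At D30, PHLDA3 had -2.02, the death receptor TNFRSF10B -1.54 and CDKN1A -3.28. At D15, PMAIP1 at -0.10 and DDB2 at -0.01 did not pass the test. The difference between the guides was tested directly. The list was lower in ZNF-G1 than in ZNF-G2 by a median of -1.41 at D15, with 19 of 20 genes lower (adjusted p = 4.77e-06 with an estimated correlation), and of -0.77 at D30, with 15 of 20 lower (adjusted p = 0.00362 with an estimated correlation). D15 PHLDA3 was no longer called with the guide libraries taken as 1 group (adjusted p = 0.0619, the highest of its alternatives).

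**Figure D3:**
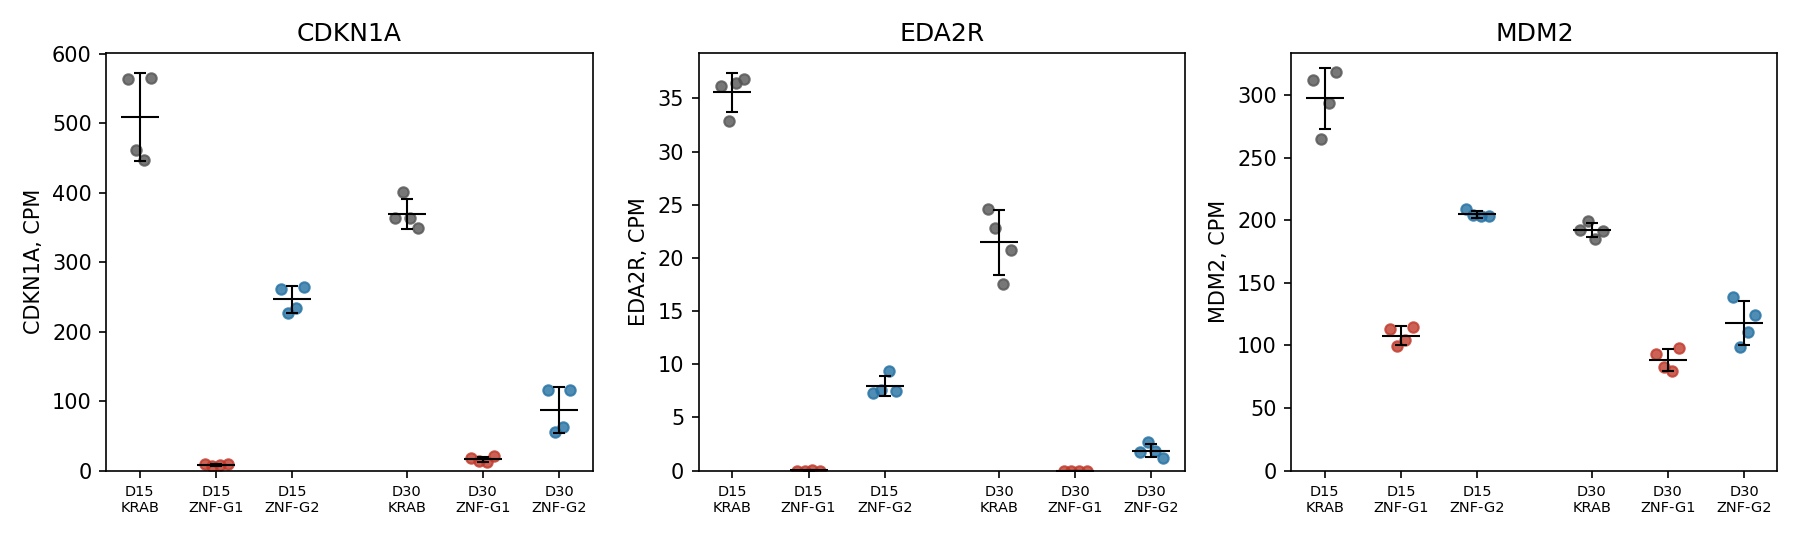
Level of CDKN1A, EDA2R and MDM2 in CPM in each library at D15 and D30, with the mean ± SD of the 4 libraries of a group. In all 3 genes the ZNF-G1 mean is the lowest of the groups, for CDKN1A at D15 8.56 against 509 in KRAB.

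Each guide was also set against KRAB on its own at D15. With ZNF-G1, 3951 genes were higher and 4252 lower, and with ZNF-G2, 3076 and 3458. In the same direction in both, 2547 genes were higher and 2956 lower, against 669 and 810 if the calls had been independent, and 29 were called in opposite directions. Both guides were set against the same KRAB libraries, which by itself makes their effects correlate. Across genes, which are not independent replicates, the effects correlated at r = 0.89, against 0.554 in 20 simulations with no guide effect. Their covariance exceeded the simulated one by 0.437. The simulations shared at most 1 call. They drew genes independently and held no effect of sample number, so their shared calls can be too few. Other splits of the real D15 libraries, which mix the groups, shared up to 412 calls. With separate pairs of KRAB libraries for the guides, 3755 to 4153 genes were shared.

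The guide lines also differed from one another at D15, in 1767 genes, 835 higher and 932 lower with ZNF-G1. PEG3 (chromosome 19, 56810077 to 56840728, minus strand), an imprinted zinc finger gene, was at 0.0898 ± 0.180 CPM with ZNF-G1, 49.7 ± 3.85 with ZNF-G2 and 62.6 ± 5.75 in KRAB (ZNF-G1 against ZNF-G2 log2 fold change -7.71, SE 0.299, adjusted p = 8.93e-10). EDA2R, a receptor gene induced by p53, had 1 count over the ZNF-G1 libraries against 1594 in KRAB, a ratio of 2660-fold (counting interval 477 to 105000), and stood at 7.93 ± 0.958 CPM with ZNF-G2. PTCHD4, a patched-domain gene, stood at 0.215 ± 0.12 CPM with ZNF-G1 and 18.2 ± 2.79 with ZNF-G2, against 54.5 ± 3.6 in KRAB. CLVS2 was higher in ZNF-G1 at 11.7 ± 1.62 CPM, against 0.0907 ± 0.108 with ZNF-G2 and 3.18 ± 0.358 in KRAB. The D15 ZNF-G1 against ZNF-G2 PEG3 value was -8.51 without ZNF-G1 replicate 4. NR2E1, a regulator of neural stem cells, differed by a log2 fold change of 2.71 and SLITRK3, a synaptic adhesion gene, by 2.65. The number of D15 genes called, ZNF-G1 against ZNF-G2, was 1096 without ZNF-G1 replicate 3.

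The same comparison in immature interneurons at D30 gave fewer genes. There, most listed p53 targets were lower with each guide, and this list alone kept its call with an estimated correlation. Most listed neural progenitor and ribosomal protein genes passed the test as lower with ZNF-G1, and fewer with ZNF-G2 (6 of 25 and 2 of 48). In the direct test between the guides neither list was called with an estimated correlation (adjusted p = 0.306 and 0.53). Of 20833 genes tested, 1985 were higher and 2881 lower, 418 and 888 of them by at least 2-fold. TWIST1, a regulator of mesenchyme, rose from 0.445 ± 0.195 CPM in KRAB to 9.52 ± 3.07 with ZNF-G1 and 24 ± 6.03 with ZNF-G2 (log2 fold change 4.81, SE 0.337, adjusted p = 2.48e-06). BCHE again fell, from 9.37 ± 1.60 CPM to 0.0602 ± 0.0695 and 0.29 ± 0.113 (log2 fold change -5.26, SE 0.31, adjusted p = 4.91e-07).

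Other rises at D30 varied between libraries of a group. HSPA6, an inducible heat shock protein gene, was at 2.91 ± 1.36 CPM in KRAB, 152 ± 192 with ZNF-G1 and 20 ± 20.9 with ZNF-G2 (log2 fold change 4.18, adjusted p = 0.0104). FOXD2, a forkhead gene, rose by 3.98, TTC6 by 3.72, TRABD2B, an antagonist of WNT proteins, by 3.53, and CMTM8 by 3.33. CMTM8 stood at 7.47 ± 2.29 CPM with ZNF-G1 and 78.9 ± 68.9 with ZNF-G2, against 2.33 ± 0.455 in KRAB. DCN, which encodes the matrix proteoglycan decorin, rose by 3.64. It reached 51.2 and 26.3 CPM in ZNF-G2 replicates 2 and 3, 8.05 and 9.32 in the other ZNF-G2 libraries, and 0.428 ± 0.217 in KRAB. D30 HSPA6 was not called in samples 2 and 3 alone (log2 fold change 2.95, adjusted p = 0.113) or with no filter on low counts (adjusted p = 0.0503), with a range of 4.02e-06 to 0.113 over its alternatives, and its log2 fold change was 3.52 without ZNF-G1 replicate 4.

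Among the falls at D30, EDA2R had 0 counts over the ZNF-G1 libraries, at least 528-fold lower than in KRAB (1581 counts), and stood at 1.87 ± 0.638 CPM with ZNF-G2 against 21.4 ± 3.02 in KRAB. TCEAL7 had a log2 fold change of -5.01, the homeobox gene HDX of -4.83, RHOJ of -4.75 and FSIP2 of -4.47. FSIP2 stood at 53.2 ± 7.40 CPM in KRAB, 2.17 ± 0.747 with ZNF-G1 and 2.44 ± 1.02 with ZNF-G2. PENK, the proenkephalin gene of striatal neurons, was at 39.9 ± 45.7 CPM in KRAB, 0.356 ± 0.157 with ZNF-G1 and 4.03 ± 1.81 with ZNF-G2 (log2 fold change -4.86, SE 1.02, adjusted p = 0.00547). The D30 PENK difference was found in samples 2 and 3, where the log2 fold change was -6.17 (adjusted p = 4.94e-11), against 1.37 in samples 1 and 4 (adjusted p = 0.081). PENK also lost its call with voom (adjusted p = 0.219, the highest of its alternatives, which ranged from 4.94e-11) and with the replicate block (0.0532), and stood at -4.14 without KRAB replicate 3.

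The D30 PRR34 log2 fold change as deposited was 7.40 (SE 2.42, adjusted p = 0.0259), and its counts were complementary to those of PRR3. That call was lost without KRAB replicate 1, 2, 3 or 4 (adjusted p = 0.0676, 0.0639, 0.0728 and 0.0707). In 7 of the 24 libraries PRR34 held 744 to 977 counts and PRR3, a neighbouring row of the table, at most 3. In the other libraries PRR3 held 277 to 1459 counts and PRR34 at most 3. The 7 libraries were 2 of D15 ZNF-G1, 3 of D30 ZNF-G1 and 2 of D30 ZNF-G2. With the values exchanged back in those libraries PRR34 was too low to be tested, and PRR3, whose deposited log2 fold changes were -0.33 at D15 (adjusted p = 0.791) and -1.26 at D30 (adjusted p = 0.515), rose by 0.25 at D15 (adjusted p = 0.00198) and 0.23 at D30 (adjusted p = 0.0297).

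**Figure D4:**
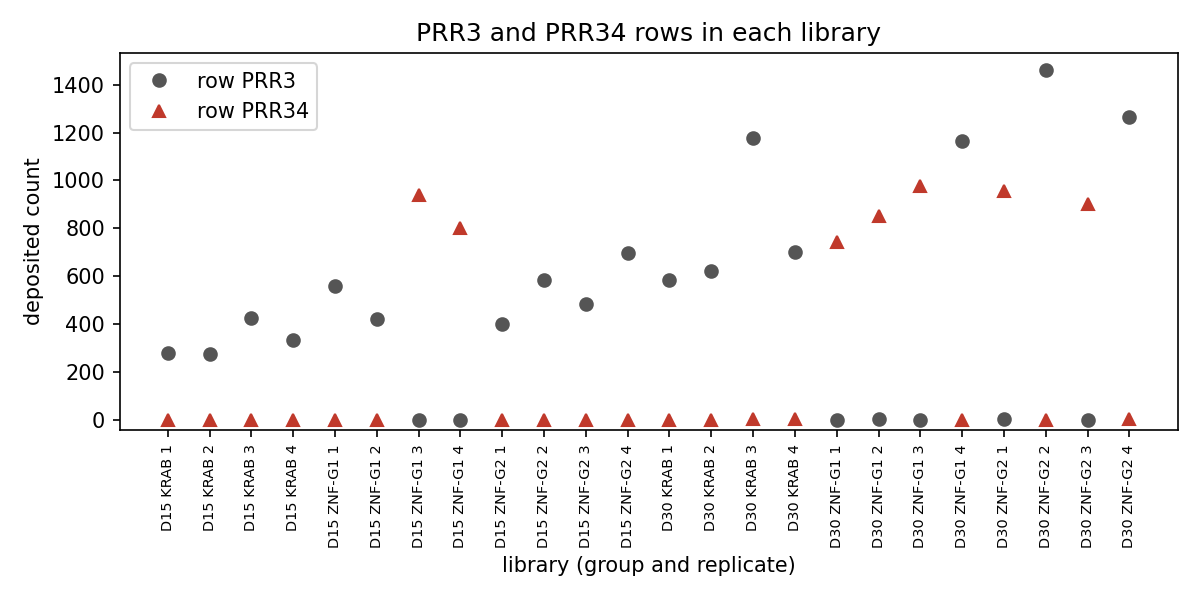
Deposited counts of the rows PRR3 and PRR34 in each of the 24 libraries. In 7 libraries, all with a guide, PRR34 holds 744 to 977 counts and PRR3 at most 3, and in the other libraries PRR34 holds at most 3.

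Neural progenitor genes were lower at D30, with more calls in ZNF-G1 than in ZNF-G2. Set against ZNF-G2 directly, ZNF-G1 had 7 of 25 lower and 0 higher (camera adjusted p = 4.42e-06, adjusted p = 0.306 with an estimated correlation). For the mean of both guides 14 of 25 tested fell, or 15 adjusted over the list alone, against 15 with ZNF-G1 alone, with 1 higher, and 6 with ZNF-G2 alone, and the median log2 fold change of the mean effect was -0.98 (camera adjusted p = 9.35e-10, adjusted p = 0.185 with an estimated correlation). FABP7 fell from 81.6 ± 12.7 CPM to 5.95 ± 0.598 and 21.4 ± 5.62, PTPRZ1, a radial glial receptor phosphatase, from 408 ± 102 to 51.4 ± 10.4 and 121 ± 54.4, and SOX1 from 194 ± 23.2 to 70.7 ± 13.9 and 140 ± 32.1. SOX2 fell by 1.06 on the log2 scale and NES fell by 1.16. Of 14 astrocyte and oligodendrocyte genes 5 fell, with 1 also higher adjusted over the list alone, S100B most at -3.14, while APOE at 0.47 did not pass the test (adjusted p = 0.00255, adjusted p = 0.185 with an estimated correlation). The median log2 fold change of the progenitor list was -0.80 in samples 1 and 4 and -1.06 in samples 2 and 3.

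The cell cycle, ribosomal and interferon lists were also called lower at D30 with the preset correlation, though few cell cycle genes passed singly, and their counts differed between the guides and between the sample pairs. With ZNF-G1 alone 13 cell cycle, 39 ribosomal and 7 interferon genes were lower, and with ZNF-G2 alone 0, 2 and 2. Set against ZNF-G2 directly, ZNF-G1 had 0, 14 and 1 lower (camera adjusted p = 0.000153, 2.1e-11 and 0.17). With an estimated correlation none of these differences was called (adjusted p = 0.679, 0.53 and 0.729). For the mean of both guides, 4 of 50 cell cycle genes fell, or 3 adjusted over the list alone, with a list median of -0.73 (adjusted p = 1.96e-06, adjusted p = 0.892 with an estimated correlation). TYMS, thymidylate synthase, had -1.10, CENPA, a centromeric histone gene, -0.57, and PCNA, the replication clamp, -0.64. The list median was -0.11 in samples 1 and 4 and -1.61 in samples 2 and 3, with 0 and 50 genes lower. With the sample pairs as a block 40 of the 50 were lower, and 36 with the replicate block. KRAB replicates 2 and 3 also stood apart in other genes, with CLIC5 at 14.8 and 17.7 CPM, MEOX1 at 4.18 and 5.05 and ALDH1A1 at 9.09 and 9.22, against at most 0.324, 0.154 and 0.308 in KRAB replicates 1 and 4. Of 48 ribosomal protein genes 34 fell, or 44 adjusted over the list alone, with RPS19 at -0.83, RPS23 at -0.45 and RPS20 at -0.58 (adjusted p = 1.11e-11, adjusted p = 0.614 with an estimated correlation). Within the pairs, 6 fell in samples 1 and 4 and 47 in samples 2 and 3. Without TMM scaling, the nuclear RNA MALAT1 stood at 5685 and 5309 CPM in KRAB replicates 2 and 3, against 8290 to 11140 in the guide libraries of the same numbers. TMM factors of 0.9452 and 0.9381 in these KRAB libraries, against 1.017 to 1.037 in these guide libraries, would narrow the gap. A difference in RNA composition between these libraries was not tested. Of 19 interferon response genes 10 fell, or 14 adjusted over the list alone (adjusted p = 0.000532, adjusted p = 0.673 with an estimated correlation). IFI44L fell from 15 ± 6.92 CPM to 0.623 ± 0.6 and 3.44 ± 2, and IFI44 and IFIT3 had -2.06 and -2.08. The calls of D30 TYMS, D30 CENPA and D30 PCNA were lost without KRAB replicate 2 (adjusted p = 0.0558, 0.0555 and 0.0679), those of TYMS and PCNA without KRAB replicate 3 (0.0681 and 0.0633), and that of PCNA without KRAB replicate 4 (0.0696) or ZNF-G1 replicate 1 (0.0505). D30 RPS23 was not called with the guide libraries as 1 group (adjusted p = 0.0609, the highest of its alternatives).

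Of 16 midbrain, hindbrain and floor plate genes at D30, 7 rose and 2 fell (adjusted p = 0.0474, adjusted p = 0.614 with an estimated correlation). The rises included the floor plate genes FOXA2 at 3.20, FOXA1 at 2.79 and CORIN at 2.33, and PAX7 at 2.98, while FGF8 had -2.44 and EN1 -1.96. The list median was -0.03 with ZNF-G1 and 0.88 with ZNF-G2, and with ZNF-G2 it was 0.504 in samples 1 and 4 and 2.47 in samples 2 and 3, where 22 genes of the list passed the filter. In ZNF-G2 replicates 2 and 3, 8 of the 16 genes were higher than in each other D30 library. Of 39 axon guidance and migration genes 4 rose and 13 fell, or 18 adjusted over the list alone, SEMA3A by a log2 fold change of -1.94 and UNC5C of -1.57, while ROBO3 rose by 1.89 (adjusted p = 0.000707, adjusted p = 0.185 with an estimated correlation). MGE and ventral patterning genes were no longer shifted as a list, with 3 of 20 higher, SHH at 1.28, LHX8 at 1.15 and GBX1 at 0.72, and 3 lower, among them NKX6-2 and DLX5 (adjusted p = 0.921). Interneuron and GABA genes had 1 higher and 6 lower of 25, with CXCR4, a chemokine receptor of migrating interneurons, at -2.05 and ERBB4 at -1.17 (adjusted p = 0.246), or 3 and 9 adjusted over the list alone. For the mean of both guides the direction depended on the sample pair, with 2 higher and 9 lower in samples 1 and 4 (median -0.543) and 7 and 8 in samples 2 and 3 (median 0.061). With ZNF-G1 alone these were 2 and 10 (-0.75) against 13 and 7 (0.604), while with ZNF-G2 alone both pairs went down, with 2 and 6 (-0.366) and 3 and 10 (-0.399). Over all ZNF-G2 libraries the list was called lower (camera adjusted p = 0.032, adjusted p = 0.554 with an estimated correlation). GAD1 at -0.08 and SST at -0.39 did not pass the test.

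The other D30 lists were not called for the mean of both guides. Pan-neuronal genes had 1 higher and 4 lower of 31, synapse and excitability genes 5 and 4 of 38, and genes of the lateral and caudal eminences and striatum 3 and 3 of 19. The hypothalamus list had 1 higher and 3 lower of 24, the neural crest and mesenchyme list 3 and 5 of 21, and the epithelium list 2 higher of 11, TTR and KRT19. The mesenchyme counts differed by guide, 3 higher and 6 lower with ZNF-G1 and 6 and 2 with ZNF-G2. The list was called higher for ZNF-G2 (camera adjusted p = 0.032, adjusted p = 0.554 with an estimated correlation). Set against ZNF-G2 directly, ZNF-G1 had 0 mesenchyme genes higher and 8 lower (camera adjusted p = 4.42e-06, adjusted p = 0.0675 with an estimated correlation). Of the dorsal pallium list, EOMES alone of 16 rose, at 1.48. The WNT pathway had 6 higher and 4 lower of 26, with RSPO3 at 2.37 and SFRP2 at -1.72, the BMP and TGF-beta list 1 and 6 of 21, and the SHH pathway 2 and 2 of 14. The stress response list had 3 and 5 of 22, hypoxia and glycolysis 3 and 3 of 22, and autism and intellectual disability genes 14 and 7 of 61. The pluripotent list had 1 and 1 of 8, the endothelial and myeloid list 2 and 2 of 8, the mitochondrial genome 2 lower of 13, and the neighbours of ZNF292 2 lower of 14, NT5E and CNR1. Cholesterol synthesis had a median of -0.08. Some of these lists turned between the sample pairs. Pan-neuronal genes had 1 higher and 12 lower in samples 1 and 4 (median -0.41) and 11 and 5 in samples 2 and 3 (0.172), synapse genes 5 and 8 (-0.0925) against 19 and 7 (0.283), and cholesterol synthesis genes 4 and 0 (0.348) against 1 and 16 (-0.435). Adjusted p-values of these lists ran from 0.0886 (epithelium) to 1 (cholesterol synthesis). Median, mean and camera direction differed in sign for the MGE, synapse, hypothalamus, neural crest, pluripotent, SHH, hypoxia and autism lists. Adjusted over the list alone, the counts were 16 and 10 for autism genes, 3 and 6 for the stress response, 1 and 7 for BMP and TGF-beta, 4 and 4 for hypoxia, and within 1 gene of those above for the rest.

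The D30 counts moved with single libraries. The number of D30 genes higher, both guides combined, was 1268, 1258 and 1129 without KRAB replicate 1, 3 or 4, and 3157 without ZNF-G1 replicate 4. That of D30 genes lower, both guides combined, was 1815, 1791 and 1697 without KRAB replicate 1, 3 or 4. In samples 1 and 4 alone 1412 genes were higher and 1845 lower, and in samples 2 and 3 alone 3466 and 5096. The counts of D15 genes higher, both guides combined, were 2689 in samples 1 and 4 and 2696 in samples 2 and 3, and those of D15 genes lower, both guides combined, 3305 and 3171.

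At D30 the guides taken singly gave unequal numbers of calls. With ZNF-G1, 2403 genes were higher and 3365 lower, and with ZNF-G2, 707 and 935. Called in the same direction with both were 435 higher and 805 lower, against 81.6 and 151 if independent, with 10 in opposite directions. Effects correlated across genes at r = 0.73, against 0.511 in the simulations, which shared 0 calls at an adjusted p under 0.05 with edgeR, and the covariance exceeded the simulated one by 0.264. These simulations again held no effect of sample number, and other splits of the real D30 libraries shared up to 577 calls. With separate pairs of KRAB libraries, 262 to 551 genes were shared. Leaving out 1 library moved the number of D30 genes called, ZNF-G2 against KRAB, from 1642 to 967, 1065, 856 or 899 (KRAB replicates 1 to 4), to 764 or 717 (ZNF-G2 replicates 2 and 3), and to 2482 (ZNF-G1 replicate 4). It moved the number of D30 genes called in both guides, same direction, from 1240 to 723, 677 or 667 (KRAB replicates 1, 3 and 4), to 581 or 571 (ZNF-G2 replicates 2 and 3), and to 1879 (ZNF-G1 replicate 4).

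ZNF-G1 and ZNF-G2 differed in 1283 genes at D30, 419 higher and 864 lower in ZNF-G1. In samples 1 and 4 alone the number was 2512 (1397 higher and 1115 lower), in samples 2 and 3 alone 3756 (1510 and 2246), and with these pairs as a block 2118 (744 and 1374). PEG3 stood at 0.951 ± 0.389 CPM with ZNF-G1, 371 ± 72.1 with ZNF-G2 and 290 ± 108 in KRAB (log2 fold change -8.48, SE 0.397, adjusted p = 9.53e-07). ZNF471, a zinc finger gene that also lies on chromosome 19 (56507843 to 56530221, plus strand), stood at 0.089 ± 0.0736, 6.61 ± 1.23 and 3.45 ± 0.872 CPM (log2 fold change -5.17). CLVS2 was again lower with ZNF-G2, at 1.16 ± 0.762 CPM against 16.8 ± 5.93 with ZNF-G1 and 14.4 ± 5.86 in KRAB. COL6A3, a collagen gene of mesenchyme, was high in ZNF-G2 replicates 2 and 3 (139 and 97 CPM) and at most 0.757 CPM in all other D30 libraries (log2 fold change -7.30, adjusted p = 0.0289). NKX2-5 stood at 26.2 ± 29.7 CPM with ZNF-G1 and 0.55 ± 0.247 with ZNF-G2 (adjusted p = 0.0247), and TYRP1, a pigment cell gene, at 6.66 ± 6.63 and 0.268 ± 0.131 (adjusted p = 0.0119). D30 ZNF-G1 against ZNF-G2 COL6A3 lost its call without ZNF-G1 replicate 1, 2, 3 or 4 (adjusted p = 0.0954, 0.0598, 0.0637 and 0.0553) or ZNF-G2 replicate 3 (0.0632), and D30 ZNF-G1 against ZNF-G2 NKX2-5 without ZNF-G1 replicate 1 (0.0691) or ZNF-G2 replicate 1, 2, 3 or 4 (0.061, 0.0502, 0.0739 and 0.0663). The log2 fold change without ZNF-G1 replicate 4 was 4.65 for NKX2-5 and 3.33 for TYRP1 (D30 ZNF-G1 against ZNF-G2 TYRP1, fitted at 4.25), and that of COL6A3 without ZNF-G2 replicate 2 was -6.38. The number of D30 genes called, ZNF-G1 against ZNF-G2, was 493 without ZNF-G1 replicate 1, 2203 without ZNF-G1 replicate 4, and 843, 602 and 626 without ZNF-G2 replicate 1, 3 or 4.

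In control cells, the listed cell cycle genes and most listed progenitor genes were lower at D30 than at D15, and most listed neuronal and interneuron genes were higher, though none of these lists kept its call with an estimated correlation. Of 21450 genes tested in KRAB, 6458 were higher at D30 and 6563 lower. The vesicular GABA transporter gene SLC32A1 rose from 3.70 ± 1.42 to 119 ± 10.4 CPM, GAD1, which makes GABA, from 3.41 ± 0.852 to 99.2 ± 22.3 (log2 fold change 4.80, SE 0.309, adjusted p = 3.57e-11), and DLX6-AS1 from 10.7 ± 3.22 to 273 ± 75.6. The MGE and ventral patterning genes DLX6, DLX2 and DLX5 rose by 4.08, 3.03 and 4.10, and the neuronal genes CELF3, ELAVL3 and INA by 2.74, 2.14 and 2.28. Of the progenitor genes, FABP7 had a log2 fold change of -1.75, HES5 of -2.37 and NES of -1.47, and of the replication genes MCM2 had -1.5, MCM7 -1.22 and PCNA -1.74. The days were deposited as separate tables, so that day and any batch between them cannot be told apart.

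By list, 26 of 30 pan-neuronal genes and 35 of 38 synapse genes, with 1 lower, rose from D15 to D30 in KRAB (camera adjusted p = 1.84e-19 and 6.14e-27), as did 16 of 25 interneuron genes, with 4 lower (2.1e-05), 9 of 20 MGE genes, with 4 lower (5.03e-05), and 44 of 61 autism and intellectual disability genes, with 9 lower (2.03e-09). Lower at D30 were all 50 cell cycle genes (2.16e-16), all 48 ribosomal protein genes (2.17e-26), all 22 cholesterol synthesis genes (8.43e-15), all 13 mitochondrial genes (0.00142), 16 of 25 progenitor genes (0.000426), 11 of 14 SHH pathway genes (2.41e-05), 13 of 20 p53 targets, with 2 higher (1.21e-05), 7 of 9 pluripotent genes, with 2 higher (0.0136), and 12 of 22 stress response genes, with 4 higher (0.0354). None of these list calls held at 0.05 with an estimated correlation, where the adjusted p values for the lists in the order given were 0.0856, 0.0627, 0.0627, 0.0627, 0.0948, 0.298, 0.101, 0.101, 0.469, 0.298, 0.121, 0.0948, 0.145 and 0.501. The other lists were not called, with higher and lower counts of 9 and 4 of 15 for dorsal pallium, 7 and 3 of 21 for the lateral and caudal eminences, 11 and 3 of 24 for hypothalamus, 6 and 5 of 19 for midbrain and hindbrain, 4 and 9 of 20 for mesenchyme, 4 and 3 of 13 for epithelium, 4 and 1 of 14 for astrocytes, and 3 and 1 of 8 for endothelium. They were 7 and 9 of 26 for WNT, 7 and 6 of 21 for BMP and TGF-beta, 6 and 8 of 22 for hypoxia, 3 and 10 of 20 for interferon, 17 and 13 of 39 for axon guidance, and 4 and 4 of 14 for the neighbours of ZNF292. Counts adjusted over the list alone differed by at most 1 gene. Median, mean and camera direction differed in sign for the epithelium, endothelium, WNT, hypoxia and neighbour lists.

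Whether the guide effect differed between the days was tested as an interaction, and 3273 genes differed, 1554 with the higher effect at D30 and 1719 with the higher effect at D15. TMEM132C had a log2 fold change of -6.56 at D15 and -0.34 at D30, where its KRAB level was already 1.18 ± 0.599 CPM against 33.3 ± 6.89 at D15. CRABP1, which binds retinoic acid, had a log2 fold change of -4.73 at D15 and 0.92 at D30 (difference 5.70, SE 0.561, adjusted p = 5.23e-07), and NKX6-1, a ventral neural tube regulator, -5.07 and -0.21. In the other direction, DLK1, an imprinted ligand gene, had 2.36 and -1.56, MME, the endopeptidase neprilysin, 2.10 and -1.63, and PENK 0.00 and -4.86. The difference of the guide effect PENK showed (adjusted p = 0.0434) was not called without D15 KRAB replicate 1, 2, 3 or 4 (adjusted p = 0.0519, 0.0691, 0.0598 and 0.0684), D15 ZNF-G1 replicate 1, 3 or 4 (0.0635, 0.0859 and 0.0603) or D15 ZNF-G2 replicate 1 (0.0502). It was also not called without D30 KRAB replicate 2 or 3 (0.0533 and 0.0625), D30 ZNF-G1 replicate 1, 2, 3 or 4 (0.0574, 0.0588, 0.0571 and 0.064) or D30 ZNF-G2 replicate 2 or 3 (0.0515 and 0.0568). Without D30 KRAB replicate 3 it was -4.19, and the difference of the guide effect MME showed was -3.02 in place of -3.71.

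Of the lists, the MGE and ventral patterning genes differed most in guide effect between the days, with 17 of 20 genes having a lower effect at D30, or 18 and 1 higher adjusted over the list alone (median difference -1.61, camera adjusted p = 5.53e-21, adjusted p = 6.68e-05 with an estimated correlation). NKX2-1 differed by -1.13. Lower effects at D30 were also called for cell cycle (8 of 50), pan-neuronal (14 of 30, with 2 higher) and progenitor genes (11 of 25, with 3 higher), and higher effects for mesenchyme (9 of 20), mitochondrial (5 of 13) and midbrain and hindbrain genes (5 of 19, with 2 lower), with adjusted p of 0.562, 0.562, 0.509, 0.409, 0.562 and 0.509 with an estimated correlation. Adjusted over the list alone, these lower effects numbered 37, 15 and 13 and these higher effects 10, 7 and 7. The p53 targets had a median difference of 0.11 and were not called (adjusted p = 0.11), nor were the other lists, at adjusted p from 0.0576 (WNT pathway) to 0.899 (interferon response), with differing signs of median, mean and test for the epithelium, SHH, hypoxia, interferon and axon guidance lists. Of genes called for the guides at both days, 602 were higher at both and 1762 lower at both, against 334 and 658 if independent, and 288 were called in opposite directions. A lasting difference between KRAB and guide cells other than ZNF292 would also recur at both days, and this overlap does not separate it. The number of genes called at D15 and D30, same direction, was 1560 without D30 KRAB replicate 4 in place of 2364.

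Median log2 fold changes of the 22 autosomes and X lay between -0.05 (chromosome 5) and 0.05 (chromosome 21) at D15, and between -0.14 (chromosome 13) and 0.12 (chromosome 16) at D30. Against random gene sets of the same size, 3 of these 23 chromosomes differed at an adjusted p under 0.05 at D15 and 15 at D30. Between ZNF-G1 and ZNF-G2, 11 differed at D15, with medians from -0.0342 to 0.04, and 18 at D30, from -0.135 to 0.178. With ZNF-G1 alone the D30 medians ran from -0.184 (chromosome 13) to 0.206 (chromosome 11). The random sets treat genes as independent and do not measure the spread between libraries, so these counts do not establish shifts of whole chromosomes.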

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

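The tests of p53 targets, of PRR34 and of the HOX genes were chosen after the result was seen, as were the splits within the sample pairs, while the other splits were chosen before it.

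Of 186 values tested for a library far from the other 3 of its group, 10 stood out, where chance gives about 1 in 20. The gap to the nearest library, as a share of the range of the group, was 0.866 for GABRB2 (replicate 3) in D15 KRAB, 0.861 for ST6GAL2 and 0.971 for RHOJ (both replicate 1) in D15 ZNF-G1, and 0.842 for FDXR (replicate 1) in D15 ZNF-G2. It was 1 for ZNF292 (replicate 4) and 1 for HOXA2 (replicate 2) in D15 ZNF-G2, each with a single count in the group. At D30 it was 0.957 for PRR34 (ZNF-G1 replicate 4), 0.886 for HSPA6 (ZNF-G2 replicate 2), 0.876 for TCEAL7 (KRAB replicate 1) and 0.91 for IFIT3 (ZNF-G1 replicate 4).

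A test of the difference itself set the guides apart in 1767 genes at D15 and 1283 at D30, and the guide effect at D30 from that at D15 in 3273 genes. Between ZNF-G1 and ZNF-G2 at D15, the log2 fold change was 5.831 for CLVS2, 2.71 for NR2E1, 2.653 for SLITRK3, -7.712 for PEG3, -5.807 for EDA2R and -5.675 for PTCHD4. At D30 it was 5.347 for NKX2-5, 4.245 for TYRP1, 3.731 for CLVS2, -8.479 for PEG3, -7.302 for COL6A3 and -5.174 for ZNF471. The guide effect differed between the days by 6.396 for TMEM132C, 5.704 for CRABP1, 4.915 for NKX6-1, -4.79 for PENK, -3.888 for DLK1 and -3.709 for MME.

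The p53 targets were lower with both guides and lowest with ZNF-G1. The D15 guide libraries were deeper than those of KRAB by 0.52 on the log2 scale. With the total of each library in the model the median log2 fold change of the list was -1.23 (upper quartile -0.851) and 17 of 20 were still lower, and within groups the list changed by a median of 0.0168 (quartiles -0.0981 and 0.0863) per doubling of the total, which argues against depth as the whole cause. In D15 ZNF-G2 alone the list median was -0.527 and 16 of 20 genes were lower, with 1 higher (camera adjusted p = 8.02e-09, but adjusted p = 0.0952 with an estimated correlation). These calls of single genes argue against a change carried by the ZNF-G1 cells alone as the whole cause. A candidate explanation for the fall shared by both guides is that these genes answer to loss of ZNF292. At D15, ZNF292 stood at 0.0599% of the KRAB level with ZNF-G1 and 0.0139% with ZNF-G2. The list medians were -1.83 and -0.527, so the ZNF292 transcript left does not account for the deeper fall with ZNF-G1. Both guides were compared with the same KRAB cells, so another difference between KRAB and guide cells is not separated from loss of ZNF292. Each guide was read in its own cells, so that a guide and a change acquired by its cells remain open for the difference between them.

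Counts of PRR34 were near 0 or at least 744 among libraries of a group. In 24 of 24 libraries 1 of the rows of PRR3 and PRR34 held at least 100 counts and the other at most 3, which is consistent with an exchange of these rows in 7 libraries. Transcription of PRR34 in some libraries alone would leave PRR3 present, and 0 of the 7 libraries with PRR34 also had 100 counts of PRR3.

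HOX genes, which mark posterior parts of the body, were present in D30 ZNF-G2 replicates 2 and 3, with 41.4 and 70.9 CPM over 39 rows and at most 4.95 in each other D30 library. HOXA5 had 107 and 188 counts there and at most 2 in each other D30 library. Some mesenchyme genes went with them, COL6A3 at 139 and 97 CPM, COL1A1 at 968 and 425 and DCN at 51.2 and 26.3, while COL3A1, at 520 and 259, was lower there than in replicates 1 and 4 (1220 and 1390). With all D30 libraries thinned to the smallest total, at least 14 HOX genes had 10 counts or more in each of the 2 libraries and at most 2 in each other, and 4 of the other libraries had a larger total than replicate 3, which argues against depth. Cells of the listed mesenchymal type cannot be told apart from other causes, since 5 of the 21 genes tested were higher in both libraries than in each other D30 library, and 3 of the 7 with less than 10 CPM in each other library, a share that meets neither bound. Of other lists, midbrain, hindbrain and floor plate had 8 of 16 such genes, the WNT pathway 7 of 26 and the lateral and caudal eminences and striatum 5 of 19. Another mixture of cells, or a difference of batch within ZNF-G2, may remain as an open explanation.

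Other splits of the libraries into groups of the same sizes were used to ask whether chance in the assignment of libraries to groups can be excluded. At D15 it can for genes higher (4002, highest other split 905), lower (4309, 683) and shared by the guides (5503, 412), for ZNF-G1 (8203, 0), ZNF-G2 (6534, 0) and ZNF-G1 against ZNF-G2 (1767, 14), and for lists called (14, 14, reached by 2 of 100 splits with the real one, with a median of 7 in the others). At D30 it can for genes higher (1985, 1395), lower (2881, 866) and shared (1240, 577), and for ZNF-G1 (5768, 18) and ZNF-G2 (1642, 3). Between the days it can for shared genes (2364, 397), for KRAB genes higher (6458, 0) and lower (6563, 0), and for the difference of the guide effect (3273, 1). In each of these but the D15 lists the real split alone, 1 split, reached its value. For the D15 lists another split also called 14. The median of 7 lists in other D15 splits shows that camera with the preset correlation often calls lists under other groupings. A list call with the preset correlation alone is therefore weak, however small its p-value. A chance difference between the KRAB, ZNF-G1 and ZNF-G2 cells would be shared by all libraries of a group and is not excluded. Splits that mix the groups also take the real differences into their spread, which can lower their counts.

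For the number of lists called at D30, which was 8, chance cannot be excluded, since 63 of 100 splits called as many. The other splits called a median of 9 and the highest called 18. With splits made within the sample pairs, 69 of 100 called as many and the highest called 16. This test is of the number and not of any single list, and the p53 targets had 17 of 20 genes lower in samples 1 and 4 and 18 of 20 in samples 2 and 3. For ZNF-G1 against ZNF-G2 at D30 chance cannot be excluded either, since 3 of 35 splits reached 1283 genes. The highest, with 2154 genes, parted samples 1 and 4 from samples 2 and 3 and points to a structure of the samples, which these splits do not keep. With the pairs as a block and splits made within them, the 18 splits are too few for a share under 0.05. There the real split gave 2118 genes and the highest other 43. Between the guides, 2512 genes differed in samples 1 and 4 alone and 3756 in samples 2 and 3 alone (D30 genes called, ZNF-G1 against ZNF-G2).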

How the results depend on the processing

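The settings with samples 1 and 4 or 2 and 3, their block, the reduced ZNF-G2 group and the exchange of PRR3 and PRR34 were added after the data were seen. Of 2483 values of named genes under an alternative, 2406 kept direction and side of the threshold, 74 lost their call and 3 reversed. A gene that fell below the filter under an alternative, as PRR34 did after the exchange, is not counted. Many alternatives leave out 1 library and share all others with the main fit. Most genes were named for large changes or small p-values in these data, so much of this agreement is built in. The recovery given for simulated data holds for 200 changed genes. Far more genes were called here, which loosens the unadjusted p needed for a call. Recovery at that threshold was not measured. Except where stated, the cause was not tested.

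The results in this paragraph are D15 genes higher, both guides; D15 genes lower, both guides; D30 genes higher, both guides; D30 genes lower, both guides, and the counts of calls named next. With no filter on low counts the D30 genes called, ZNF-G1 against ZNF-G2, numbered 846, with more genes tested. DESeq2 gave 2246 of these, 2815 D30 genes called, ZNF-G2 against KRAB, and 2043 D30 genes called in both guides, same direction. With voom D30 had 3049 higher, 4443 lower, 3474 for ZNF-G2 and 2529 shared. The replicate block gave 3180 D15 genes called, ZNF-G1 against ZNF-G2, and 2627 for ZNF-G2 and 2040 shared at D30. The pairs block gave 3404 for ZNF-G2, 2118 between guides and 2600 shared at D30. A test against a fold of 1.2 gave 1670 higher and 2277 lower at D15 and 657 and 1291 at D30, and the fit of all 24 libraries 3583 higher at D30. With an estimated correlation, D15 gene lists called numbered 1 and D30 gene lists called 1, and with fry 22 at D15. Splitting the KRAB libraries left a median of 304.5 shared at D30.

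With fewer samples, samples 1 and 4 gave 714 D15 genes called, ZNF-G1 against ZNF-G2, and at D30 1845 D30 genes lower, both guides, 1090 D30 genes called, ZNF-G2 against KRAB, 2512 D30 genes called, ZNF-G1 against ZNF-G2, and 1386 genes called at D15 and D30, same direction. D30 PENK reversed to 1.373 and the difference of the guide effect PENK showed to 0.937. Samples 2 and 3 gave 4074 D15 genes called, ZNF-G2 against KRAB, 957 between guides and 3434 D15 genes called in both guides, same direction. At D30 they gave 3466 D30 genes higher, both guides, 5096 lower, 7072 for ZNF-G2, 3756 between guides and 4881 D30 genes called in both guides, same direction, with 5323 genes with a different guide effect at D30 and D15. With D30 ZNF-G2 reduced to samples 1 and 4, 981 were higher, 1597 lower, 361 called for ZNF-G2, 277 shared and 1456 shared between days, and D30 ZNF-G1 against ZNF-G2 COL6A3 reversed to 0.01698, its high libraries being left out.

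Leaving out 1 library gave 1096 to 1977 D15 genes called, ZNF-G1 against ZNF-G2, 1129 to 3157 D30 genes higher, both guides, 1697 to 3643 D30 genes lower, both guides, 717 to 2482 D30 genes called, ZNF-G2 against KRAB, 493 to 2203 D30 genes called, ZNF-G1 against ZNF-G2, 571 to 1879 D30 genes called in both guides, same direction, and 1560 to 3033 genes called at D15 and D30, same direction. Residuals of libraries with the same number correlated at 0.0479 to 0.285 at D15, where 11 of 12 libraries were closest to their own number, and at -0.0425 to 0.483 at D30, where 6 of 12 were. At D30 the mean was 0.149 within samples 1 and 4 or 2 and 3 and -0.149 across them. Residuals cancel within a group, so the mean across mirrors the mean within. The pairs were formed after these libraries were seen, so neither value tests them.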

Other observations

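RNU6-1, a gene for the U6 small nuclear RNA, was at 0.0478 ± 0.0557 CPM in D15 KRAB, 24.3 ± 2.74 with ZNF-G1 and 44.1 ± 2.45 with ZNF-G2, and at 0.115 ± 0.115, 18.5 ± 5.48 and 27.2 ± 5.32 at D30. All 16 guide libraries lay above every KRAB library. Guide and KRAB cells thus differed in this row as well as in ZNF292, and the cause was not tested. The comparison with KRAB does not separate loss of ZNF292 from other differences between these cells. RNU6-2, another U6 gene, was at 0.284 ± 0.175, 0.191 ± 0.045 and 0.27 ± 0.274 CPM at D15.

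CAT, the catalase gene, was near 0 in the ZNF-G1 cells, as were PEG3 and ZNF471. CAT had no counts in D15 ZNF-G1, against 3.4 ± 0.0618 CPM in KRAB and 2.84 ± 0.845 with ZNF-G2, and at D30 stood at 0.15 ± 0.0914 with ZNF-G1, 4.09 ± 1.67 in KRAB and 7.9 ± 1.41 with ZNF-G2. ZNF471 stood at 0.0696 ± 0.0846 CPM in D15 ZNF-G1, 1.03 ± 0.301 in KRAB and 1.06 ± 0.207 with ZNF-G2. In D30 ZNF-G1 replicate 4 the nuclear RNA MALAT1 stood at 18530 CPM and NEAT1 at 571.6, both without TMM scaling, against 5309 to 13430 for MALAT1 in the other D30 libraries.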
